A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

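Footprints of 8 libraries of W303 yeast were measured by ribosome profiling: wild type and grr1-deficient cells at 0 h and 4 h of tunicamycin, 2 libraries per group, which the design text calls biological replicates. Per the labels' protocols, cells grew at 30 °C in synthetic complete medium with 2% glucose from an OD600 of 0.2. Per the labels' protocols, tunicamycin was added to 1 µg/ml, cycloheximide was in the lysis buffer, and lysate with 20 µg of RNA was digested with 1.25 units of RNase I per µg of RNA for 45 min. The linkers carried a random barcode of 5 nt. The submitters' processing notes name cutadapt 2.6, Bowtie2 2.3.5, STAR 2.7.3a, DESeq2 (no version given) and genome build R64, without their order.

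Per the file headers, the count tables hold raw counts of footprints of 25 to 100 nt with a unique alignment, each assigned to 1 nucleotide by an offset from its 5′ end that depends on its length (plastid), in coding regions, annotated UTRs and transcripts. The deposited RPKM values of the same tables were used only to recover the library totals that the authors used, 2457969 to 4696702 reads, of which 50.4% to 65.8% lay in coding regions. The deposited codon tables give reads per codon as RPM (reads relative to library size), from which whole reads were recovered with a tolerance of 0.01, as a ratio (reads over the gene's mean reads per codon) and, per gene, as a signal (reads per nucleotide). They list only genes of at least 0.167 reads per nucleotide in that library, 1054 to 1735 genes, with 741 in all 8 libraries. The authors' comparison tables give log2 fold changes of 4 h over 0 h within each genotype, with a DESeq2 test score that is not used here, and p-values, for footprints and for translation efficiency. Their RNA-seq libraries were not analysed here, so no change of footprints was separated from a change of mRNA except through the authors' values.

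The tables hold 6696 regions, of which 6008 matched the reference annotation by locus name. Coding counts were analysed with edgeR 4.0.16 in R 4.3.3. Of these regions, filterByExpr on the 4 groups left 5314 genes. TMM factors (0.753 to 1.25) scaled the libraries, and a quasi-likelihood F test was made on a model with 1 mean per group. The 5 contrasts were 4 h against 0 h in each genotype, their difference (the interaction), and grr1 against the wild type at each time. All p-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Those of genes, codons and polarity measure the spread between samples. Levels are CPM, counts relative to the TMM-scaled library size, with the SD over 2 libraries. The SE is the size of the log2 fold change over the square root of its F value. With few footprints in a group it can be smaller than the counting error. The median SE of a log2 fold change was 0.231, 0.232, 0.327, 0.227 and 0.235 in the 5 contrasts. Log2 fold changes of genes with 0 footprints in a group are given as a bound against a floor of 3 counts over the group, and those with 1 to 3 counts as a ratio with an exact conditional 95% interval. Intervals and floors cover counting error only. The interactions of GRR1 and BAP3 are fitted values on such counts, and their size is not used.

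A set of 30 gene lists was tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation. Camera sets the members of a list against the other genes, and the preset correlation treats genes as nearly independent. Its p-values then depend on the number of genes and are not a measure of the spread between samples. The lists are ER chaperones and oxidative folding, ER-associated degradation, N-glycosylation, ER translocation, ER-Golgi transport, phospholipid and inositol synthesis, ergosterol synthesis, cell wall remodelling, and calcineurin-Crz1 targets. Others are cytosolic ribosomal proteins, ribosome biogenesis, translation factors, amino acid synthesis, the sulfur amino acid pathway, the environmental stress response, heat shock chaperones, the proteasome, glycolysis, and TCA cycle and respiration. The remaining ones are hexose transport and sensing, amino acid permeases, SCF-Grr1 components and substrates, G1/S and histone genes, phosphate starvation, the iron regulon, pheromone response, a-specific and alpha-specific genes, mitochondrially encoded genes and auxotrophic marker genes. Calls of list members are also given adjusted over the list alone.

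The genes named in the text were chosen by rule. GRR1, UBP3, BRE5, HAC1, IRE1, TRL1, MOT2, RPS7A, RPS7B and KAR2 are always named. For each comparison over time the 10 genes with the largest rise and the 10 with the largest fall are named, and for the other comparisons the 6 highest and the 6 lowest. These were drawn from genes past the threshold with a log2 fold change of at least 1 in size, a mean of at least 20 CPM in the higher group, the same direction in both same-numbered pairs of libraries and a standard symbol. From each list up to 4 members with the smallest adjusted p may be named, and "led by" refers to this order and not to the size of the change. The contrasts, tests, lists, this rule and the first set of alternatives were fixed before the data were examined.

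Codon occupancy was taken from the 741 genes in all 8 codon tables. The ratio at each position was averaged over the positions of each of 61 sense codons, with the first and last 20 codons of each gene left out. Its log2 was tested with limma. The deposited tables name the codons in the E, P and A site of each position, and the A site codon was used. Reads at the position with the start codon in the P site were 0.760 to 1.275 of the gene mean, against 0.267 to 0.444 at the following 19 positions. Polarity is the mean position of a gene's footprints, from -1 at the start to 1 at the stop codon, and was tested with limma over 741 genes. Shares of HAC1 footprints have exact (Clopper-Pearson) 95% intervals from scipy 1.17.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the rest.

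The steps were tested on simulated data with known changes (5261 genes at the depths of the libraries). Each gene had 1 spread for all groups, and same-numbered libraries were not linked. In the data the grr1 replicates lay further apart than those of the wild type. The numbers below therefore do not show how the tests fare with unequal spreads. For the wild type over time, edgeR called 41 of 100 genes changed 2-fold and 96 of 99 genes changed 4-fold, with 4 false calls. For the interaction it called 11 of 100 and 70 of 99 with 5 false calls, and for the genotypes at 4 h 40 of 100 and 94 of 99 with 4 false calls. With no change put in, there were 0 false calls for grr1 over time and 2 for the genotypes at 0 h. DESeq2 1.42.0 called 45 of 100 and 95 of 99, with 11 false calls. Camera found the 1 changed list with either correlation and called 0 of the other lists falsely. The genes were drawn independently of each other. The simulation therefore does not show how either correlation fares on lists whose members vary together. Limma found 9 of 10 codons changed by 0.6 on the log2 scale, with 1 false call. It found 99 of 100 genes with polarity changed by 0.3, with 4 false calls. Smaller changes, such as the median polarity difference of -0.0325 between the genotypes at 0 h, were not simulated.

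The alternatives chosen then were RLE factors, total-count scaling, DESeq2, no filter on low counts, a mean of at least 50 counts, and a fit of only the groups compared. Others were a replicate term over all libraries or within each genotype, a 2-fold minimum, ribosomal protein genes left out, and each library left out in turn. Lists were also tested with fry, and codons and polarity with other weights, ends and gene choices. Alternatives chosen after seeing the data were fits without both grr1 replicate 2 or both replicate 1 libraries, counts recovered from the codon tables, the P site for codons and 5′ UTR footprints without YDR133C.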

Results

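Ribosome profiling, which sequences the mRNA fragments that ribosomes protect (footprints), was done in 8 libraries of W303, a laboratory strain of budding yeast. Wild-type and grr1-deficient cells (grr1) were sampled at 0 h and 4 h of tunicamycin, an inhibitor of N-linked glycosylation that loads the endoplasmic reticulum (ER) with unfolded proteins. Each of the 4 groups had 2 biological replicates. Coding regions held 3010656 and 2578928 footprints in the wild type at 0 h, and 1297749 and 1828689 at 4 h. In grr1 they held 2741529 and 1735154 footprints at 0 h, and 1272645 and 1536281 at 4 h. Across the 5314 genes tested, the levels of the replicates correlated at r = 0.990 in the wild type at 0 h, 0.978 in the wild type at 4 h, 0.946 in grr1 at 0 h and 0.956 in grr1 at 4 h. Genes are not independent replicates. No library without tunicamycin was sampled at 4 h, so the drug and the 4 h of culture changed together in every comparison over time.

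GRR1 (YJR090C, chromosome X, 590872 to 594327), which encodes the F-box protein that picks substrates for the SCF ubiquitin ligase, held 128 and 103 footprints in the wild type at 0 h and 122 and 248 at 4 h. It held 0 and 0 footprints in grr1 at 0 h and 2 and 4 at 4 h. Against a floor of 3 footprints over the group, GRR1 was at least 79.1-fold lower in grr1 than in the wild type at 0 h. At 4 h the ratio of wild type to grr1 was 49 (95% counting interval 22.3 to 134). In the wild type GRR1 rose with a log2 fold change of 0.81 ± 0.20 (SE, n = 2 libraries per group, adjusted p = 0.0081 by edgeR). That call ended without wild type 0 h replicate 1 (0.69, adjusted p = 0.0924), without wild type 0 h replicate 2 (0.64, adjusted p = 0.108) and without wild type 4 h replicate 2 (0.56, adjusted p = 0.0943). DESeq2 did not make it either (0.66, adjusted p = 0.14), while the authors' deposited DESeq2 table did (0.70, adjusted p = 0.034).

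The first comparison asked which genes changed their footprints between 0 h and 4 h of tunicamycin in the wild type. HAC1 (YFL031W, chromosome VI, 75179 to 76147), which encodes the transcription factor of the unfolded protein response, rose from 65.8 ± 29.7 to 2255 ± 6.64 CPM (mean ± SD, n = 2). CPM are footprint counts relative to the TMM-scaled library size. Its log2 fold change was 5.09 ± 0.37 (SE, adjusted p = 2.6e-05 by edgeR). KAR2 (YJL034W, chromosome X, 381327 to 383375), the main ER chaperone, rose from 1079 ± 10.8 to 3735 ± 417 CPM, a log2 fold change of 1.79 ± 0.23 (adjusted p = 0.000207). ERO1, which drives disulfide formation in the ER, rose by 3.31 ± 0.24 on the log2 scale, and SIL1, an exchange factor for Kar2, by 3.03 ± 0.22. In the opposite direction, each of the 136 cytosolic ribosomal protein genes measured fell, with a median log2 fold change of -3.52.

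The genes with the largest rises in the wild type were PHM7, YET2, ULI1, GPG1, IGD1, BAG7, HSP26, FUN19, HSP12 and DCS2. PHM7 held 2 footprints at 0 h and 155 at 4 h, a normalised ratio of 86.9 (95% counting interval 23.7 to 724). YET2, an ER membrane protein gene, went from 2.26 to 153 CPM (log2 fold change 6.0 ± 0.25, adjusted p = 1.98e-05). ULI1, a gene induced by the unfolded protein response, went from 10.2 to 592 (5.83 ± 0.43, adjusted p = 2.67e-05). The small heat shock genes HSP26 and HSP12 rose by 5.26 ± 0.75 and 5.11 ± 0.86 on the log2 scale (adjusted p = 0.000355 and 0.000946). The largest falls were those of DBP2, PHO11, PHO12, PHO5, PHO3, RPL22B, RPL9A, INA1, RPS9B and ASC1. DBP2, an RNA helicase gene, went from 613 to 27.9 CPM (log2 fold change -4.49 ± 0.37, adjusted p = 3.21e-05). ASC1, which encodes a protein of the small ribosomal subunit, went from 6213 to 392 (-3.99 ± 0.48, adjusted p = 0.000133). The acid phosphatase gene PHO5 had a log2 fold change of -4.30 ± 0.49 (adjusted p = 0.000105); PHO11 and PHO12 are near-identical copies, so their separate values are uncertain.

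The study's title names a pathway from Grr1 over Ubp3 to HAC1. UBP3 (YER151C, chromosome V, 469686 to 472424), which encodes a deubiquitinase, held 76.0 ± 6.25 CPM at 0 h and 72.4 ± 0.267 at 4 h in the wild type. Its log2 fold change of -0.07 ± 0.15 did not pass the test (adjusted p = 0.706), and with total-count scaling it was 0.60 and did pass (adjusted p = 0.00853). BRE5, the cofactor of Ubp3, fell by 0.54 ± 0.19 on the log2 scale (adjusted p = 0.0331). The BRE5 call ended with DESeq2 (adjusted p = 0.0664) and with a minimum mean of 50 counts (adjusted p = 0.0537), and with total counts its value was 0.13. It also ended without wild type 0 h replicate 1 (-0.61, adjusted p = 0.0849) and without wild type 4 h replicate 1 (-0.33, adjusted p = 0.191). MOT2, a ubiquitin ligase gene, rose by 0.95 ± 0.18 (adjusted p = 0.00164). TRL1, the tRNA ligase that joins HAC1 exons, fell by 1.26 ± 0.29 on the log2 scale (adjusted p = 0.00523), a call that ended with total counts (-0.59, adjusted p = 0.0972). IRE1, the sensor kinase of the pathway, did not pass the test (-0.57 ± 0.28, adjusted p = 0.114; 0.10 with total counts), and passed it without wild type 4 h replicate 1 (-0.98, adjusted p = 0.0295). RPS7A (chromosome XV, 505794 to 506767) and RPS7B (chromosome XIV, 443398 to 444315) encode the ribosomal protein whose ubiquitin Ubp3 removes. They fell by 3.54 ± 0.36 and 3.18 ± 0.24 on the log2 scale (adjusted p = 6.84e-05 and 2.77e-05).

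**Figure D1:**
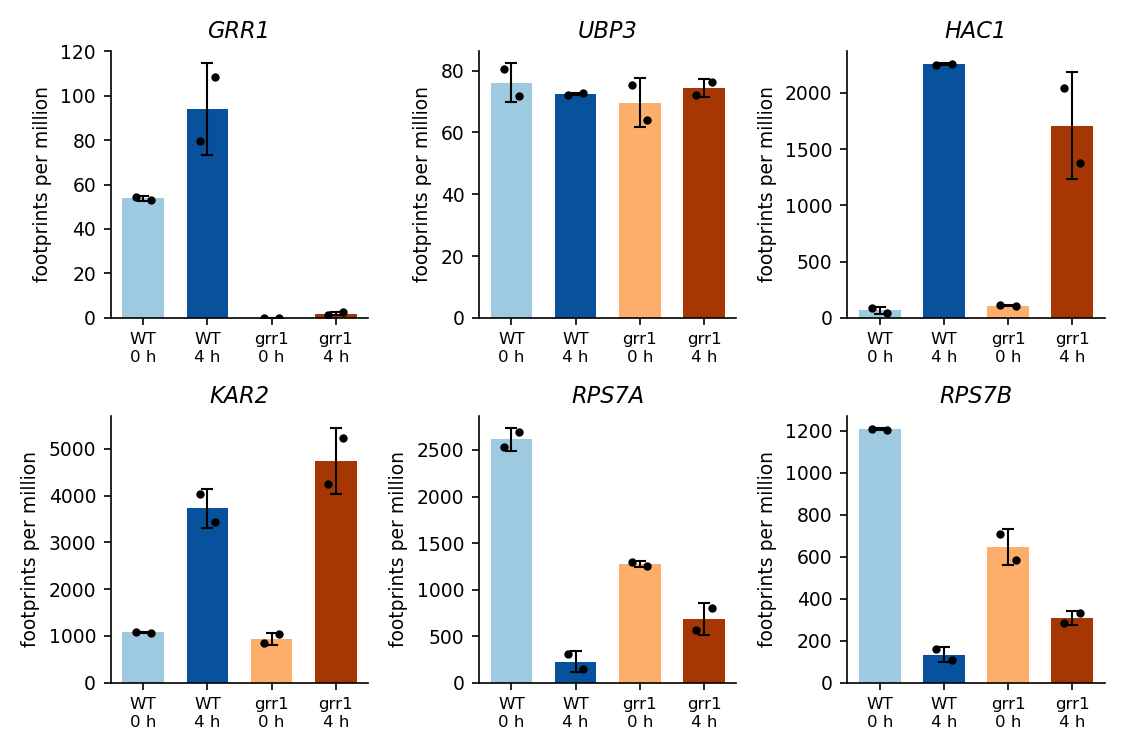
Footprints in CPM (y axes) of GRR1, UBP3, HAC1, KAR2, RPS7A and RPS7B in the 4 groups, with bars at the mean, error bars of 1 SD and points for the 2 libraries per group. UBP3 lay between 69.6 and 76.0 in every group mean, while HAC1 means were 65.8 and 109 at 0 h and 2255 and 1710 at 4 h.

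In the wild type, 1759 of the 5314 genes rose and 1433 fell (60.1% of those tested); 3403 genes had an unadjusted p under 0.05, and DESeq2 called 1148 up and 1338 down. Of the calls, 55.1% were up, against 48.1% with RLE factors and 78.8% with total counts. Total-count scaling moved the median log2 fold change of all genes from 0.17 to 0.84 in this comparison and from -0.13 to -0.66 in the interaction. It moved that between the genotypes from 0.04 to 0.40 at 0 h and from -0.02 to -0.19 at 4 h, and that of grr1 over time from 0.02 to 0.16. Directions of gene lists are therefore relative to the scaling used, under which the median gene need not lie at 0.

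Of the 30 gene lists, 14 differed from the other genes in the wild type by camera with a preset correlation. None of these calls held with an estimated correlation (smallest adjusted p = 0.37), and neither did any list call of the other comparisons (smallest adjusted p = 0.106). Ribosomal protein genes (adjusted p = 6.28e-36) had their smallest adjusted p at RPS22B (-3.25 ± 0.24), which fell less than the list median of -3.52. Values within their near-identical pairs are uncertain. All 52 ribosome biogenesis genes fell (median -2.43, adjusted p = 2.03e-21), among them UTP8 (-2.56 ± 0.16) and NOP7 (-2.91 ± 0.19). Of 39 translation factor genes, 38 fell and 0 rose (median -1.80, adjusted p = 6.32e-14), and of 48 amino acid synthesis genes 42 fell and 1 rose (median -1.51, adjusted p = 6.1e-12). Of 34 genes of the environmental stress response, 33 rose and 0 fell (median 3.50, adjusted p = 1.63e-10), led by the glucokinase gene GLK1 (4.24 ± 0.21) and the trehalose synthase gene TSL1 (4.97 ± 0.28). Adjusted over the list alone, these 5 lists gave the same numbers of calls.

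The ER lists moved less as wholes in the wild type. Of 23 ER chaperone and oxidative folding genes, 12 rose and 6 fell, and 12 and 6 adjusted over the list alone, with a median of 0.72 that camera did not separate from other genes (adjusted p = 0.177). Of 18 ER-associated degradation genes, 11 rose and 3 fell (11 and 3 adjusted over the list alone; median 0.92, adjusted p = 0.0777), led by DER1 (3.22 ± 0.21). The N-glycosylation list had 11 genes that rose and 8 that fell, with a median of -0.00, a mean of 0.08 and a test direction of up (adjusted p = 1.00). ER translocation genes (median -0.11, adjusted p = 0.332) and ER-Golgi transport genes (median 0.49, adjusted p = 0.0641) did not pass. Phospholipid and inositol synthesis genes (median -0.48, adjusted p = 0.10) and cell wall genes (median 1.02, adjusted p = 0.0742) did not pass either. With total counts, the medians of N-glycosylation, ER translocation, phospholipid synthesis and ergosterol synthesis were positive (0.67, 0.55, 0.19 and 0.33), against -0.34 for ergosterol synthesis with TMM (adjusted p = 0.0469).

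Further wild-type calls concerned calcium signalling, metabolism and mating. Targets of calcineurin and Crz1 rose in 10 of 14 cases and fell in 0 (median 1.68, adjusted p = 0.00118), with PMC1 at 2.41 ± 0.18 and RCN1 at 2.67 ± 0.20. Heat shock chaperones had 16 of 25 up and 1 down (median 1.06, adjusted p = 0.0020). In the proteasome 20 of 33 genes rose (21 adjusted over the list alone; median 0.44, adjusted p = 0.00133), including that of its transcription factor RPN4 (2.18 ± 0.24). Genes of the TCA cycle and respiration had a median of 0.89 (15 of 44 up, 0 down, 11 up adjusted over the list alone; adjusted p = 0.00435). Without both grr1 replicate 2 or both replicate 1 libraries 40 were up and 1 down (medians 0.88 and 0.83). Glycolysis genes had one of -0.84 (0 up, 12 of 18 down; 1 up and 12 down adjusted over the list alone; adjusted p = 0.00462). The sulfur amino acid pathway (median -0.86, adjusted p = 0.00435), phosphate starvation genes (median -1.28, adjusted p = 0.00356) and mating type a-specific genes (median -2.38, adjusted p = 0.00442) were low as groups. The a-specific receptor gene STE2 fell by 3.15 ± 0.28 on the log2 scale.

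Lists without a camera call in the wild type were hexose transport and sensing (median 0.09, mean 0.08, test direction down, adjusted p = 0.899) and amino acid permeases (-0.72, adjusted p = 0.0603). The others were SCF-Grr1 components and substrates (0.50, adjusted p = 0.0984), G1/S and histone genes (-0.58, adjusted p = 0.21) and the iron regulon (-0.54, adjusted p = 0.378). Pheromone response genes (median 0.03, mean -0.16, adjusted p = 0.448) and alpha-specific genes (median -0.78, test direction up, adjusted p = 0.849) were not called. Neither were mitochondrially encoded genes (1.15, adjusted p = 0.241) or auxotrophic marker genes (-0.70, adjusted p = 0.183). Within these lists the G1 cyclin genes CLN2 and CLN1 rose by 1.39 ± 0.18 and 1.12 ± 0.15. PCL1 rose by 2.86 ± 0.20, and the iron uptake gene FET3 fell by 3.61 ± 0.39 on the log2 scale. With total counts the medians of the G1/S list and the iron regulon were 0.08 and 0.12, and with RLE those of hexose transport and pheromone response were -0.07 and -0.12.

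The next comparison asked the same of grr1 cells. HAC1 rose from 109 ± 2.85 to 1710 ± 473 CPM in grr1 (n = 2), a log2 fold change of 3.97 ± 0.35 (SE, adjusted p = 0.000685 by edgeR). KAR2 rose from 941 ± 132 to 4738 ± 701 CPM (2.33 ± 0.24, adjusted p = 0.000951). ULI1 had the largest log2 fold change, 5.11 ± 0.42 (adjusted p = 0.000667), from 11.04 to 399 CPM. ERO1 went from 155 to 1139 and SIL1 from 55.0 to 414, log2 fold changes of 2.87 ± 0.24 and 2.90 ± 0.22 (adjusted p = 0.000667 for each). The other leading rises in grr1 were those of DIA1 (3.76 ± 0.25), YET2 (3.38 ± 0.21), MNC1, RTA1, GIP1 and ICT1.

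The largest falls in grr1 were those of AIM33, FIT2, DSE2, SCW11, AIM20, EGT2, FET3, RKI1, RGI2 and HNT1. DSE2, SCW11 and EGT2, which serve daughter cell separation, fell by 2.84 ± 0.36, 2.76 ± 0.28 and 2.68 ± 0.36 on the log2 scale (adjusted p = 0.00184, 0.000929 and 0.00202). FET3, a high-affinity iron oxidase gene, went from 465 to 75.3 CPM (-2.63 ± 0.37, adjusted p = 0.00237). The AIM33 call (-3.76 ± 1.09, adjusted p = 0.0343) ended without either wild type 0 h library (-3.76, adjusted p = 0.0616). It also ended without grr1 0 h replicate 1 (-1.42, adjusted p = 0.323), 4 h replicate 1 (-4.65, adjusted p = 0.107) or 4 h replicate 2 (-3.17, adjusted p = 0.14). The FIT2 call (-3.28 ± 0.79, adjusted p = 0.0169) ended without grr1 0 h replicate 1 (-1.40, adjusted p = 0.0578), 4 h replicate 1 (-3.24, adjusted p = 0.0928) or 4 h replicate 2 (-3.34, adjusted p = 0.0679). RKI1 (-2.56 ± 0.81, adjusted p = 0.0446) lost its call without wild type 0 h replicate 1 or 2 (-2.55 each, adjusted p = 0.0783 and 0.078). It was -0.84 without grr1 0 h replicate 1 (adjusted p = 0.367), and the call also ended without grr1 4 h replicate 1 or 2 (-2.71 and -2.43, adjusted p = 0.15 and 0.148).

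Of the pathway genes, RPS7B fell in grr1 (-1.08 ± 0.23, adjusted p = 0.00987), a call that ended without grr1 4 h replicate 1 (-0.97, adjusted p = 0.0737). RPS7A did not pass (-0.90 ± 0.33, adjusted p = 0.0728) but passed with DESeq2 (-0.91, adjusted p = 0.028) and without wild type 4 h replicate 1 or 2 (-0.90 each, adjusted p = 0.0203 and 0.0204). UBP3 (0.09 ± 0.16, adjusted p = 0.696), BRE5 (-0.07 ± 0.20, adjusted p = 0.81) and IRE1 (0.07 ± 0.27, adjusted p = 0.854) did not pass the test. Neither did TRL1 (-0.77 ± 0.30, adjusted p = 0.0903) or MOT2 (0.31 ± 0.18, adjusted p = 0.219). TRL1 passed it without grr1 0 h replicate 2 (-1.13, adjusted p = 0.00853). In that fit UBP3 and IRE1 were at -0.02 and -0.12, and IRE1 was at -0.04 without grr1 4 h replicate 1.

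In grr1, 679 genes rose and 832 fell (28.4% of those tested); 2224 had an unadjusted p under 0.05, and DESeq2 called 387 up and 670 down. The count was 618 without grr1 4 h replicate 1 and 741 in a fit of the 4 grr1 libraries alone. Of the calls, 44.9% were up, 43.6% with RLE factors and 57.8% with total counts. Deviations of same-numbered grr1 libraries from their group means correlated at r = 0.525 (across genes), which the main model ignores. A replicate term within each genotype gave 1941 genes in grr1. The main model also shares 1 spread per gene between all groups, though the grr1 replicates lay further apart than those of the wild type.

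By camera 17 of the 30 lists differed from other genes in grr1. Of 23 ER chaperone genes 14 rose and 1 fell (14 and 3 adjusted over the list alone; median 1.12, adjusted p = 3.35e-07), with MPD1 and JEM1 at 2.04 ± 0.18 and 1.78 ± 0.16 beside SIL1 and ERO1. ER-Golgi transport genes had 21 of 31 up and 2 down (22 and 2 adjusted over the list alone; median 0.75, adjusted p = 1e-06), led by the cargo receptor gene ERV29 (1.47 ± 0.16). ER-associated degradation (7 up, 0 down, 8 and 0 adjusted over the list alone; median 0.45, adjusted p = 0.00212) was also high. So was N-glycosylation (10 up, 0 down, the same adjusted over the list alone; median 0.37, adjusted p = 0.0074). Calcineurin targets had 9 of 14 up and 0 down (median 1.13, adjusted p = 7.5e-06), including YPS1 (1.98 ± 0.18). Of the 136 ribosomal protein genes, 79 fell (133 adjusted over the list alone; median -1.03, adjusted p = 7.55e-17), and of 52 ribosome biogenesis genes 35 fell (43 adjusted over the list alone; median -0.86, adjusted p = 6.21e-14). These numbers depended on the grr1 replicate: 122 and 45 fell without both replicate 2 libraries (medians -1.27 and -1.11), and 5 and 18 without both replicate 1 libraries (-0.79 and -0.60). Stress response genes had 9 of 34 up and 0 down, also adjusted over the list alone (median 0.67, adjusted p = 9.84e-05). Without both replicate 2 libraries 21 were up (median 1.18), and without both replicate 1 libraries 10 (median 0.50). TCA cycle and respiration genes were low in grr1 (median -0.58, adjusted p = 0.0485), a call that ended without both grr1 replicate 1 libraries (median 0.05, adjusted p = 0.757) and with RLE factors (adjusted p = 0.0503). The iron regulon fell in 9 of 15 cases and rose in 1 (9 and 2 adjusted over the list alone; median -0.94, adjusted p = 0.0147). The G1/S and histone list fell in 12 of 20 and rose in 2 (median -0.58, adjusted p = 0.0074). Without both replicate 1 libraries 5 genes of this list fell, and 3 ER-associated degradation genes rose. The medians of ergosterol synthesis, glycolysis, phosphate starvation and a-specific genes, all uncalled, lay between -0.09 and -0.03 and were positive with total counts. For glycolysis the mean was 0.04, and for amino acid permeases the median of 0.13 stood beside a test direction of down.

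Whether the responses of the genotypes differed was tested as the interaction, in which a positive value means a higher log2 fold change over time in grr1 than in the wild type. The ribosomal protein genes fell less in grr1, with all 136 past the threshold and a median interaction of 2.45. RPS7A had an interaction of 2.64 ± 0.47 (SE, n = 2 libraries per group, adjusted p = 0.00778 by edgeR) and RPS7B one of 2.10 ± 0.32 (adjusted p = 0.00594). RPS7A went from 2613 ± 119 to 226 ± 112 CPM in the wild type and from 1275 ± 32.1 to 685 ± 174 in grr1 (mean ± SD). The stress response genes went the opposite way (28 of 34 past the threshold, median -2.94), with GLK1 at -3.20 ± 0.27 (adjusted p = 0.0013). HAC1 had an interaction of -1.12 ± 0.44, which did not pass the threshold (adjusted p = 0.0955).

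**Figure D2:**
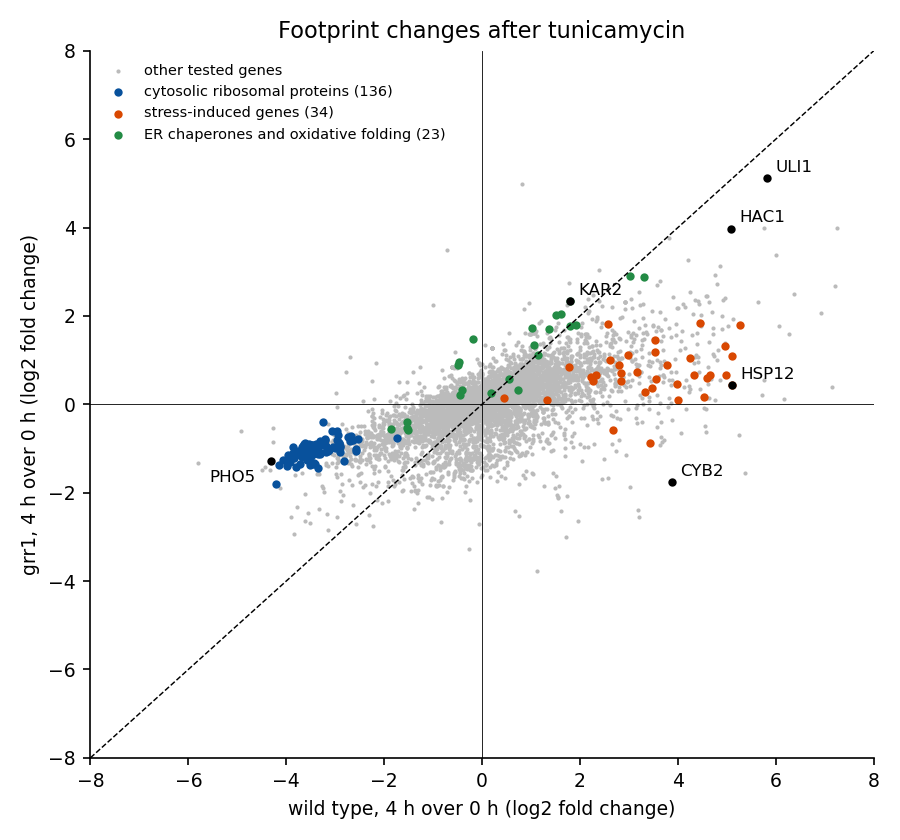
Log2 fold change of footprints from 0 h to 4 h in the wild type (x axis) and in grr1 (y axis), 1 point for each of 5314 genes, 3 gene lists in colour and equal change dashed. Ribosomal protein genes had medians of -3.52 in the wild type and -1.03 in grr1, and ER chaperone genes 0.72 and 1.12.

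The HAC1 interaction passed with total counts (-1.64, adjusted p = 0.0226), with a replicate term within each genotype (-1.20, adjusted p = 0.0391) and without both grr1 replicate 1 libraries (-1.33, adjusted p = 0.0453). KAR2 (0.54 ± 0.32, adjusted p = 0.239), UBP3 (0.16 ± 0.22, adjusted p = 0.623) and BRE5 (0.47 ± 0.27, adjusted p = 0.226) did not pass. The same held for IRE1 (0.64 ± 0.39, adjusted p = 0.253), TRL1 (0.50 ± 0.42, adjusted p = 0.417) and MOT2 (-0.64 ± 0.25, adjusted p = 0.0919). MOT2 passed with total counts (-1.17, adjusted p = 0.0106) and without grr1 0 h replicate 2 (-0.78, adjusted p = 0.0415), and TRL1 passed without grr1 0 h replicate 1 (1.10, adjusted p = 0.0354). With total counts UBP3, BRE5 and TRL1 were at -0.37, -0.06 and -0.04. The fitted GRR1 interaction (4.17 ± 1.25, adjusted p = 0.045) rested on 0 and 6 footprints in grr1, so its size is not known (0.71 and 0.75 in the same-numbered pairs of libraries), and its call ended without any 1 of the 8 libraries (adjusted p = 0.0515 to 0.152).

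The highest other interactions were those of SST2, OPT1, BAP3, PHO11 and PHO5, and the lowest those of CYB2, IGD1, GPG1, TMA10, AGX1 and IDP2. SST2, which switches off the pheromone receptor signal, went from 75.1 to 11.5 CPM in the wild type and from 2.26 to 5.34 in grr1 (3.78 ± 0.55, adjusted p = 0.00556). CYB2, the lactate dehydrogenase gene, went from 3.16 to 48.2 in the wild type and from 286 to 84.6 in grr1 (-5.63 ± 0.80, adjusted p = 0.00531). TMA10, a stress-induced gene, went from 22.6 to 544 and from 765 to 498 (-5.19 ± 0.40, adjusted p = 0.0013). OPT1 (3.51 ± 0.78) lost its call without grr1 4 h replicate 2 (2.83, adjusted p = 0.141), as did PHO5 (3.01 ± 0.86; 2.08, adjusted p = 0.306) and PHO11 (3.02 ± 0.83; 2.21, adjusted p = 0.236). PHO5 and PHO11 also lost it without wild type 0 h replicate 1 (adjusted p = 0.0578 and 0.0591) or 2 (adjusted p = 0.08 and 0.0713). PHO11 lost it also without wild type 4 h replicate 2 (2.35, adjusted p = 0.0707). BAP3 (3.25 ± 0.88), with 1 and 4 footprints in the grr1 groups and thus of unknown size, lost its call on 6 of the 8 omissions (adjusted p = 0.0515 to 0.127). It passed without wild type 0 h replicate 1 or grr1 0 h replicate 1, and DESeq2 did not call it (adjusted p = 0.0963). AGX1 (-5.03 ± 1.48) lost its call on omission of each library but grr1 0 h replicate 2 (adjusted p = 0.0521 to 0.152; value -2.06 without grr1 0 h replicate 1). IDP2 (-4.70 ± 1.43) lost it on omission of each library but grr1 0 h replicate 2 and grr1 4 h replicate 1 (adjusted p = 0.0804 to 0.151; value -2.74 without grr1 0 h replicate 1).

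In the interaction 652 genes were higher and 719 lower (25.8% of those tested); 2111 had an unadjusted p under 0.05, and DESeq2 called 589 higher and 371 lower. Of the calls, 47.6% were higher, against 58.6% with RLE factors and 15.9% with total counts. With a replicate term within each genotype 1791 genes passed. The count was 725 without wild type 0 h replicate 1, 638 without replicate 2 and 643 without wild type 4 h replicate 2. The time changes of the 5314 genes in the genotypes correlated at r = 0.664 (rho 0.692, across genes), and the SD of the changes in grr1 was 0.513 of that in the wild type. Of the calls, 618 rose in both genotypes (224.76 expected for independent calls) and 582 fell in both (224.36 expected).

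By camera 18 lists differed in the interaction. Ribosomal proteins (adjusted p = 2.02e-40) and ribosome biogenesis (44 of 52 higher, 49 adjusted over the list alone; median 1.57, adjusted p = 1.08e-22) were higher. So were translation factors (29 of 39 higher, 35 adjusted over the list alone; median 1.13, adjusted p = 1.71e-14) and amino acid synthesis (22 higher and 1 lower of 48, 26 and 1 adjusted over the list alone; median 0.98, adjusted p = 1.72e-09). Stress response genes (0 higher, 28 lower, 30 lower adjusted over the list alone; adjusted p = 4.63e-13) were lower. TCA cycle and respiration genes had a median of -1.51 (12 of 44 lower, also over the list alone; adjusted p = 2.1e-06). It was -1.69 without both grr1 replicate 2 libraries (44 lower) and -0.85 without both replicate 1 libraries (29 lower). ER chaperone genes were higher (6 of 23 higher, 0 lower, 7 and 0 adjusted over the list alone; median 0.51, adjusted p = 0.00205), but their median was -0.03 with total counts. Among them were LHS1 (1.66 ± 0.26) and the mannosyltransferase gene PMT2 (1.42 ± 0.24). The medians of N-glycosylation, ER translocation, ER-Golgi transport, phospholipid synthesis, ergosterol synthesis and the sulfur pathway, 0.26 to 0.49 and called higher, were -0.27 to -0.05 with total counts. The phospholipid call also ended without both grr1 replicate 2 libraries (adjusted p = 0.216). For the pheromone response list the median was -0.19, the mean 0.26 and the test direction up (adjusted p = 0.328), and for the G1/S list the median was 0.03 and the mean -0.24 (adjusted p = 0.475). CLN1 and PCL1 were lower in the interaction (-1.25 ± 0.22 and -1.82 ± 0.27).

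**Figure D3:**
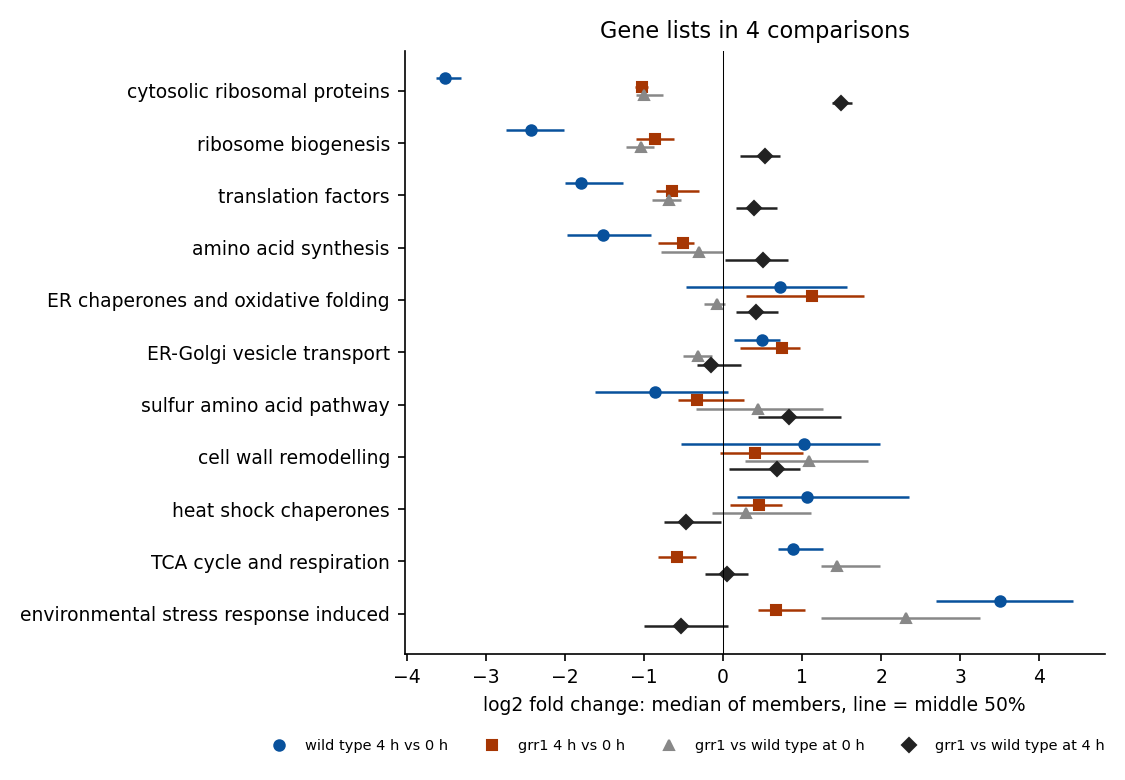
Median log2 fold change (x axis) of the measured members of 11 gene lists in 4 comparisons, with lines over the middle 50% of members. Ribosomal proteins lay at -3.52 in the wild type over time, -1.03 in grr1 over time, -0.99 between the genotypes at 0 h and 1.49 at 4 h, and the medians of ER chaperones (-0.08), ER-Golgi transport and amino acid synthesis at 0 h were positive with total counts.

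The genotypes were then compared before treatment. At 0 h grr1 cells had far fewer footprints on the amino acid permease genes BAP3 and TAT1. BAP3 held 849 footprints in the wild type and 1 in grr1, a normalised ratio of 872 (95% counting interval 156 to 34500). TAT1 went from 182 in the wild type to 2.58 CPM in grr1 (log2 fold change -6.27 ± 0.33, SE, n = 2 libraries per group, adjusted p = 5.67e-05 by edgeR). It held 3 and 7 footprints in the grr1 libraries, so its SE does not cover counting error. The oligopeptide transporter gene OPT1 went from 121 to 1.33 (-6.40 ± 0.35, adjusted p = 5.67e-05). MIG2, a glucose-induced repressor gene, held 184 footprints in the wild type and 3 in grr1, a ratio of 63 (21.2 to 308), and the glucose transporter gene HXT1 had a log2 fold change of -4.50 ± 0.38. PHO3 was lower in grr1 (447 to 8.80 CPM, -5.63 ± 0.66, adjusted p = 0.000534).

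The genes highest in grr1 at 0 h were FBP1, JEN1, RGI2, DPA10, DSF1 and MAN2, and the replicates differed widely in most of them. FBP1, a gluconeogenic gene, held 0 footprints in the wild type and 142 in grr1, at least 46.1-fold higher, and RGI2 held 0 and 96, at least 31.1-fold higher. JEN1, the lactate permease gene, held 1.70 CPM in the wild type and 652 ± 844 (SD) in grr1 (log2 fold change 8.42 ± 1.76, adjusted p = 0.00613). Without wild type 0 h replicate 2 it was 7.43 (adjusted p = 0.058). The ratios were 440 (78.6 to 17400) for DPA10, 214 (58.9 to 1770) for DSF1 and 159 (43.7 to 1320) for MAN2. Without grr1 0 h replicate 1 the calls of DPA10 (4.62, adjusted p = 0.315) and FBP1 (5.12, adjusted p = 0.0685) ended. Without grr1 0 h replicate 2 those of DSF1 (4.79, adjusted p = 0.192) and MAN2 (4.37, adjusted p = 0.225) did. All 4 also ended without either wild type 0 h library (adjusted p = 0.0761 to 0.149).

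RPS7A and RPS7B were lower in grr1 at 0 h (-1.03 ± 0.33, adjusted p = 0.0349, and -0.90 ± 0.22, adjusted p = 0.0129). The RPS7A call ended on omission of any 1 of the 4 libraries compared (-1.21 to -1.01, adjusted p = 0.0675 to 0.0951) and with total counts (-0.67, adjusted p = 0.103). The RPS7B call ended without grr1 0 h replicate 2 (-0.77, adjusted p = 0.0533) and with total counts (-0.53, adjusted p = 0.0607). HAC1 (0.72 ± 0.32, adjusted p = 0.108), KAR2 (-0.20 ± 0.23, adjusted p = 0.517), UBP3 (-0.12 ± 0.15, adjusted p = 0.549) and BRE5 (-0.47 ± 0.19, adjusted p = 0.074) did not pass. Nor did IRE1 (0.12 ± 0.26, adjusted p = 0.755), TRL1 (-0.55 ± 0.27, adjusted p = 0.142) or MOT2 (0.16, adjusted p = 0.492). HAC1 passed with total counts (1.08, adjusted p = 0.0312), BRE5 with RLE factors (-0.59, adjusted p = 0.0301) and TRL1 without grr1 0 h replicate 1 (-1.13, adjusted p = 0.00603). UBP3 and KAR2 were at 0.24 and 0.17 with total counts.

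At 0 h 1217 genes were higher and 899 lower in grr1 (39.8% of those tested); 2616 had an unadjusted p under 0.05, and DESeq2 called 893 and 816. The count was 1226 without wild type 0 h replicate 1 and 1170 without replicate 2. Of the calls, 57.5% were higher, 47.9% with RLE factors and 83.8% with total counts. The difference at 0 h correlated with the change over time in the wild type at r = 0.589 (rho 0.626, across genes). Because both use the wild type 0 h libraries, noise alone gave a mean r of 0.488 in 100 simulations, but a covariance of 0.0507 against 1.13 in the data. With the wild type 0 h replicates split between the comparisons, r was 0.555 and 0.556. Of the calls, 673 were higher in both and 703 lower in both, numbers for which the shared libraries leave no simple expected value.

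By camera 18 lists differed at 0 h. TCA cycle and respiration genes were higher in 27 of 44 cases and lower in 0 (32 and 0 adjusted over the list alone; median 1.44, adjusted p = 2.77e-07), with IDH1 at 2.27 ± 0.19. The median was 2.02 without both grr1 replicate 2 libraries (44 higher) and 0.51 without both replicate 1 libraries (24 higher). Stress response genes were higher in 26 of 34 (29 adjusted over the list alone; median 2.32, adjusted p = 2.05e-09), with ALD4 at 4.83 ± 0.33. Cell wall genes were higher in 19 of 30 cases and lower in 1 (median 1.08, adjusted p = 2.9e-05), with PIR3 at 4.57 ± 0.43. Ribosome biogenesis genes were lower in 48 of 52 cases (50 adjusted over the list alone; median -1.03, adjusted p = 3.24e-17). Ribosomal protein genes were lower in 73 of 136 (103 adjusted over the list alone; median -0.99, adjusted p = 1.12e-10). Phosphate starvation genes were lower in 12 of 14 cases and higher in 1 (median -1.54, adjusted p = 3.32e-07), with the polyphosphate synthesis gene VTC3 at -2.91 ± 0.17. Amino acid permeases were lower in 11 of 22 and higher in 3 (12 and 3 adjusted over the list alone; median -0.62, adjusted p = 0.00424). Glycolysis genes had a median of -0.70 (4 of 18 lower; adjusted p = 0.00203), with 13 lower without both grr1 replicate 2 libraries (median -0.93) and 6 lower and 1 higher without both replicate 1 libraries (median -0.52). The pheromone response (median -1.06, adjusted p = 0.0113) and a-specific lists (median -1.22, adjusted p = 0.0044) were lower, calls that ended without both grr1 replicate 1 libraries (adjusted p = 0.151 and 0.0676). The hexose list had 7 higher and 5 lower of 16 (7 and 6 adjusted over the list alone; median -0.12, adjusted p = 0.778), with the invertase gene SUC2 at 2.79 ± 0.36. With total counts the medians of ER translocation, ER-Golgi transport, phospholipid synthesis, amino acid synthesis and the G1/S list, all called lower (-0.34 to -0.24), were 0.02 to 0.12. The calls of phospholipid synthesis, amino acid synthesis and the G1/S list ended without both grr1 replicate 2 libraries (adjusted p = 0.0949, 0.0678 and 0.0767). The amino acid synthesis median was -0.17 in that fit and -0.66 without both replicate 1 libraries. The ER-associated degradation median of 0.01 stood beside a mean of -0.03 and was -0.11 with RLE factors.

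The last gene-level comparison set grr1 against the wild type after 4 h of tunicamycin. SUL1, a sulfate permease gene, held 13.2 CPM in the wild type and 478 in grr1 (log2 fold change 5.17 ± 0.37, SE, n = 2 libraries per group, adjusted p = 0.000371 by edgeR). BAP3 remained low in grr1 (99.8 to 1.32, -6.17 ± 0.32, adjusted p = 0.000104), as did HXT1 (511 to 16.5, -4.95 ± 0.40, adjusted p = 0.000684) and TAT1 (-4.32 ± 0.37, adjusted p = 0.000873). In the grr1 libraries BAP3 held 2 and 2 footprints and TAT1 3 and 5, so their SEs do not cover counting error. RPS7A and RPS7B were higher in grr1 at 4 h (1.60 ± 0.34, adjusted p = 0.0181, and 1.21 ± 0.23, adjusted p = 0.0138). The transcripts of the G1 cyclins CLN1 and CLN2, whose proteins are Grr1 substrates, had fewer footprints in grr1 (-1.26 ± 0.16 and -1.41 ± 0.18).

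The other genes highest in grr1 at 4 h were FIT3 (4.76 ± 0.51, adjusted p = 0.00184), the cell wall gene PIR3 (571 against 6197 CPM, 3.44 ± 0.40) and SFK1 (3.22 ± 0.35). MAL12 and MAL32 (4.49 ± 0.68 and 4.36 ± 0.66) are near-identical copies whose separate values are uncertain. Both lost their calls without wild type 4 h replicate 2 (4.32 and 4.00, adjusted p = 0.0681 for each). The lowest were MIG2, with 192 footprints in the wild type and 1 in grr1 (ratio 152, 27.0 to 6050), BAP3, GRR1, HXT1, TAT1 and the serine deaminase gene CHA1 (387 against 26.0, -3.88 ± 0.26). The RPS7A and RPS7B calls ended without wild type 4 h replicate 2 (1.17 and 0.94, adjusted p = 0.0706 and 0.0791) or grr1 4 h replicate 2 (1.32 and 1.09, adjusted p = 0.105 and 0.0781). HAC1 (-0.40 ± 0.30, adjusted p = 0.39), KAR2 (0.34 ± 0.22, adjusted p = 0.315), UBP3 (0.04 ± 0.16, adjusted p = 0.893) and BRE5 (0.01 ± 0.20, adjusted p = 0.987) did not pass. Nor did IRE1 (0.76 ± 0.29, adjusted p = 0.107), TRL1 (-0.05, adjusted p = 0.928) or MOT2 (-0.47 ± 0.17, adjusted p = 0.0987). MOT2 passed with total counts (-0.64, adjusted p = 0.0443), with which UBP3 and BRE5 were at -0.13 and -0.17.

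At 4 h 541 genes were higher and 292 lower in grr1 (15.7% of those tested); 1766 had an unadjusted p under 0.05, and DESeq2 called 442 and 131. The count was 113 without wild type 4 h replicate 2, 198 without grr1 4 h replicate 2, and 428 without wild type 4 h replicate 1. It was 439 and 448 without wild type 0 h replicate 1 and 2, and 1719 without both grr1 replicate 1 libraries. Of the calls, 64.95% were higher, 66.7% with RLE factors and 40.9% with total counts.

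By camera 16 lists differed at 4 h. Ribosomal protein genes were higher in 127 of 136 cases (135 adjusted over the list alone; median 1.49, adjusted p = 7.02e-41). The sulfur pathway was higher in 13 of 25 cases and lower in 1 (16 and 2 adjusted over the list alone; median 0.84, adjusted p = 1.78e-07), with MET2 at 2.28 ± 0.21. Amino acid synthesis genes were higher in 15 of 48 and lower in 1 (21 and 1 adjusted over the list alone; median 0.50, adjusted p = 1.33e-05), with TRP3 at 1.62 ± 0.19 and the regulator gene GCN4 at 2.06 ± 0.32. ER chaperone genes were higher in 6 of 23 cases (8 adjusted over the list alone; median 0.42, adjusted p = 0.00201), with LHS1 at 1.84 ± 0.19. Stress response genes were lower in 8 of 34 cases and higher in 1 (11 and 1 adjusted over the list alone; median -0.53, adjusted p = 0.00255). G1/S and histone genes were lower in 6 of 20 (7 adjusted over the list alone; median -0.34, adjusted p = 0.000149). The SCF-Grr1 list, GRR1 included, was lower in 6 of 19 and higher in 1 (7 and 1 adjusted over the list alone; median -0.40, adjusted p = 0.017). Mitochondrially encoded genes were lower in 4 of the 6 measured (6 adjusted over the list alone; median -3.68, adjusted p = 0.00201), with OLI1 at -4.27 ± 0.89. The size of this difference depended on the replicate 2 libraries, which held few such footprints: the median was -2.68 without them and -6.32 without both replicate 1 libraries. Counts within lists depended on the grr1 replicate at 4 h too. Without both replicate 2 libraries 23 amino acid synthesis genes were higher and 1 lower, and 1 stress gene was higher and 16 lower (median -0.70). Without both replicate 1 libraries 11 ER chaperone genes were higher and 0 lower, and 6 stress genes were higher and 13 lower (median -0.25). For hexose transport the median was 0.30 and the mean -0.55 (test direction down, adjusted p = 0.624), and for calcineurin targets -0.19 and 0.20 (up, adjusted p = 0.921). For TCA cycle and respiration genes a median of 0.05, -0.11 with total counts, stood beside a test direction of down (adjusted p = 0.921). The grr1 replicates went opposite ways on this list: it was higher without both replicate 2 libraries (13 higher, 0 lower, median 0.37, adjusted p = 3.4e-05) and lower without both replicate 1 libraries (2 higher, 20 lower, median -0.38, adjusted p = 4.09e-06).

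**Figure D4:**
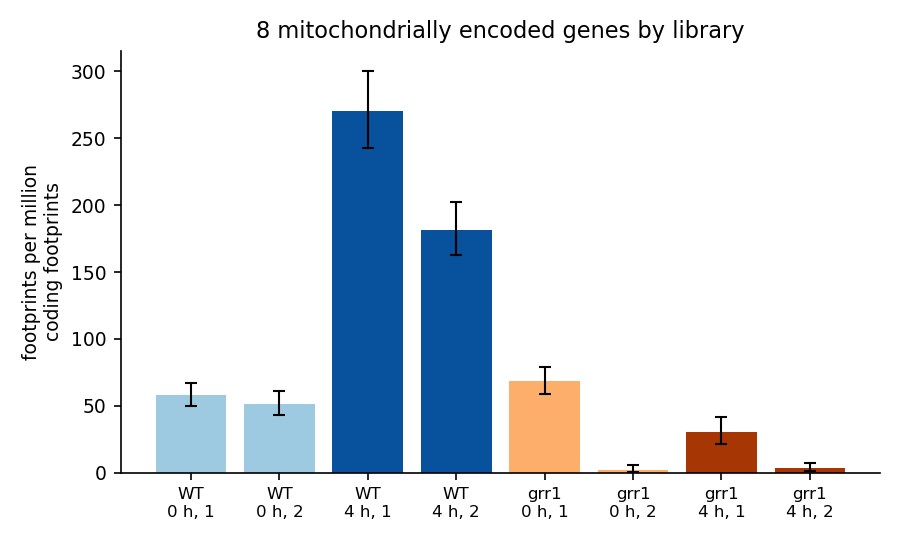
Footprints on 8 mitochondrially encoded genes relative to all coding footprints, in CPM without TMM factors (y axis), in each library, with exact 95% intervals of the counts. The grr1 replicate 2 libraries lay at 2.31 and 3.26, the other 6 between 30.6 and 270.5.

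Codon-resolved values of 741 genes were compared by the codon that the deposited tables give for the ribosomal A site, where the next tRNA binds. At 0 h ribosomes of grr1 stood more often on the tryptophan codon TGG, with reads relative to the gene mean of 2.64 and 4.06 in grr1 against 1.43 and 1.47 in the wild type. The log2 difference was 1.18 ± 0.18 (SE, n = 2, adjusted p = 0.00494 by limma). Leucine codons TTA and TTG were lower in grr1 at 0 h (-0.47, adjusted p = 0.00376, and -0.88 ± 0.16, adjusted p = 0.00855), as was the histidine codon CAT (-0.57, adjusted p = 0.00494). At 4 h TGG was at 1.68 and 1.69 in the wild type and 2.67 and 2.28 in grr1 (0.55, adjusted p = 0.139). It passed the test without grr1 0 h replicate 1 or 2 (0.55, adjusted p = 0.0028 for each).

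Between genotypes, 9 codons were higher and 8 lower at 0 h (23 at an unadjusted p under 0.05), and 1 higher and 5 lower at 4 h (13 unadjusted). Over time 11 codons rose and 7 fell in the wild type (23 unadjusted), led by GCA (-0.45 ± 0.04, adjusted p = 0.00105), and limma called 0 of the 61 codons in grr1 (11 unadjusted). The interaction held 5 higher and 4 lower (21 unadjusted). Single libraries set these counts. In the wild type 1 codon passed without 0 h replicate 1 or 4 h replicate 2, 7 without 4 h replicate 1 and 9 without 0 h replicate 2. Between the genotypes at 0 h 2 codons passed without wild type replicate 1 (TGG 1.16, adjusted p = 0.051) and 9 without replicate 2. At 4 h 0 codons passed without wild type 4 h replicate 1 or 2, 1 without grr1 4 h replicate 2 and 2 without wild type 0 h replicate 1 or 2. In the interaction leaving out 1 library gave 1 to 12. With the codon in the P site TGG was lower in grr1 at 0 h (-0.40, adjusted p = 0.0423), and with the codon in the E site 0 codons passed in each comparison (7 to 12 unadjusted).

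**Figure D5:**
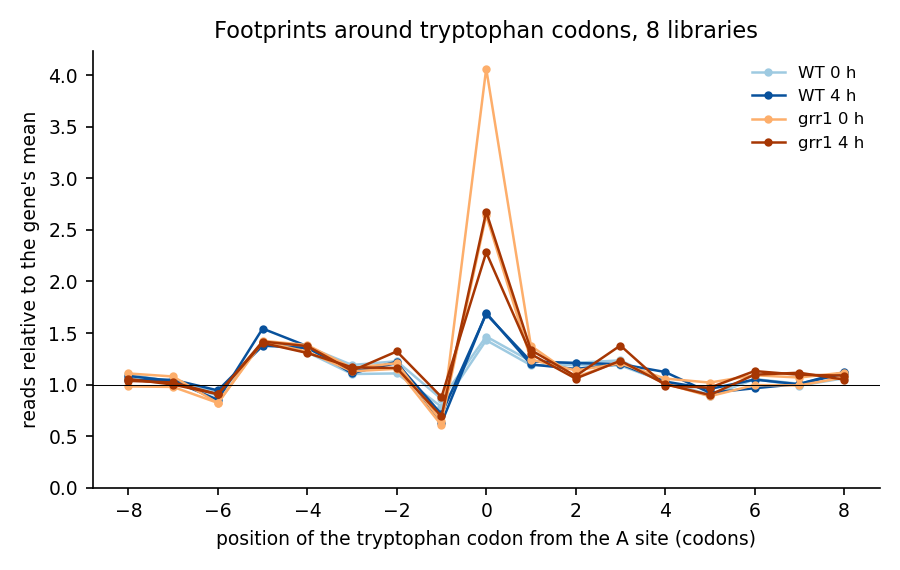
Mean reads relative to the gene mean (y axis) at codons around tryptophan codons, by offset in codons from the A site (x axis), 1 line per library. At offset 0 the grr1 0 h libraries reached 2.64 and 4.06 and the wild type 0 h libraries 1.43 and 1.47.

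Some of the same 741 genes had footprints nearer to the start codon in grr1 at 0 h. Polarity runs from -1 at the start to 1 at the stop codon. Its median change at 0 h was -0.0325, with 74.6% of genes negative, and limma called 0 genes higher and 47 lower (187 at an unadjusted p under 0.05). The median polarity was 0.113 and 0.103 in the wild type and 0.0951 and 0.0591 in grr1 at 0 h. With the ends of the genes left out 1 gene passed at 0 h. RPP2B had the smallest adjusted p (-0.197 ± 0.032, adjusted p = 0.0135). The number was 0 without wild type 0 h replicate 1 or grr1 0 h replicate 2, 4 without wild type 0 h replicate 2, 27 without grr1 0 h replicate 1 and 16 without either grr1 4 h library. At 4 h 0 genes were higher and 5 lower (136 unadjusted), and 0 to 3 lower on omission of any 1 library. With the 371 genes of higher coverage 71 genes were lower at 0 h, 40 lower at 4 h, and 1 higher and 20 lower over time in the wild type. Over time limma called 0 genes in the wild type (95 unadjusted), 1 higher and 8 lower in grr1 (53 unadjusted) and 0 in the interaction (53 unadjusted); the calls in grr1 ended without any 1 of the 8 libraries.

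Along the HAC1 coding region, the codons behind the intron, which splicing joins to the rest, held 8.45% (exact 95% interval 7.48 to 9.50) and 10.2% (9.37 to 11.2) of the HAC1 footprints in the wild type at 4 h. In grr1 at 4 h they held 8.03% (7.01 to 9.15) and 8.48% (7.29 to 9.80). At 0 h the share was 5.75% (2.79 to 10.3) in wild type replicate 1, 9.45% (6.15 to 13.7) and 8.02% (4.34 to 13.3) in grr1. HAC1 was below the depth limit of the codon table of wild type 0 h replicate 2. The differences between the genotypes lay within the counting intervals or the spread between replicates.

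The authors' deposited tables compared 4 h with 0 h within each genotype, for footprints and for translation efficiency, which relates footprints to RNA-seq that was not analysed here. In the authors' tables the translation efficiency of HAC1 rose by 4.76 ± 0.34 on the log2 scale in the wild type (DESeq2, adjusted p = 7.8e-39) and by 3.79 ± 0.40 in grr1 (adjusted p = 1.2e-16). That of KAR2 did not pass in either genotype (-0.56, adjusted p = 0.0648, and -0.28, adjusted p = 1). RPS7B had a deposited change of 1.24 ± 0.23 in the wild type (adjusted p = 1.28e-05) and 0.09 in grr1 (adjusted p = 1). RPS7A did not pass in either genotype (1.18 ± 0.41, adjusted p = 0.0586, and 0.67 ± 0.39, adjusted p = 1). The median change of translation efficiency of ribosomal protein genes was 0.90 in the wild type and 0.50 in grr1, and that of ER chaperone genes -0.30 and -0.22. The authors' tables called 192 genes up and 160 down of 5088 in translation efficiency in the wild type, and 1 up and 8 down of 5220 in grr1. The difference between the genotypes in translation efficiency was not tested. The authors' footprint tables called 1272 up and 1430 down of 5111 in the wild type and 269 and 493 of 5240 in grr1. Their fold changes correlated with those of edgeR at r = 1.00 in each genotype (across genes).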

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

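Chosen only after the results were seen were the tests of depth, of general loss and of a lost mitochondrial genome, the test of tryptophan uptake, and the tests of scaling and of the levels before treatment. Most of what follows drew attention because the genotypes responded differently over time by the test of the interaction, which held 1371 genes.

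Among named genes, interactions were positive for SST2 (3.78), OPT1 (3.51), PHO11 (3.02), PHO5 (3.01), RPS7A (2.64) and RPS7B (2.10). The fitted values of GRR1 (4.17) and BAP3 (3.25) rested on 6 and 5 footprints in grr1. The GRR1 call ended without any 1 library and the BAP3 call without 6 of the 8, so their size is not known. They were negative for CYB2 (-5.63), IGD1 (-5.52), GPG1 (-5.21), TMA10 (-5.19), AGX1 (-5.03) and IDP2 (-4.70). Single omitted libraries ended the calls of OPT1 (1 of 8), PHO5 (3), PHO11 (4), AGX1 (7) and IDP2 (6), and without grr1 0 h replicate 1 AGX1 and IDP2 were at -2.06 and -2.74. Gene lists with a positive interaction were cytosolic ribosomal proteins (median 2.45), a-specific genes (2.25), ribosome biogenesis (1.57), phosphate starvation (1.33), translation factors (1.13), amino acid synthesis (0.98) and glycolysis (0.84). Smaller positive medians were those of ER chaperones (0.51), phospholipid and inositol synthesis (0.49), the sulfur pathway (0.46), ER translocation (0.41), N-glycosylation (0.33), ergosterol synthesis (0.28) and ER-Golgi transport (0.26). Those with a negative one were the environmental stress response (-2.94), TCA cycle and respiration (-1.51), calcineurin targets (-0.59) and heat shock chaperones (-0.57). With total counts the medians of the lists between 0.26 and 0.51 were negative.

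Codons with an interaction in the A site were GCA (0.59), CAT (0.54), TGT (0.39), TTA (0.36) and GCC (0.30) on the positive side and ATA (-0.43), AAA (-0.41), GGA (-0.33) and TAT (-0.26) on the negative side. A signal outside the main measurement lay in annotated 5′ UTRs, which held 2.297 footprints per 1000 coding footprints in the wild type at 4 h, above the 1.29 of the wild type at 0 h (mean of 2 libraries each).

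The grr1 replicate 2 libraries held nearly no mitochondrially encoded footprints, 4 at 0 h and 5 at 4 h. Lower depth was excluded, since 4 footprints were 3.36% of the 119 expected from grr1 replicate 1, whose lower limit was 98. A general loss of mitochondrial ribosome footprints in preparation stays open. The region Q0092 held 20 and 21 footprints in these libraries and 0 or 1 in the others, but 1 region cannot decide this. A mitochondrial genome lost or rearranged in the cells behind these libraries may also be the source. The labels do not state whether same-numbered libraries come from 1 culture, though deviations from the group mean correlated at r = 0.525 (across genes) between the grr1 libraries of the same number. Nuclear TCA cycle and respiration genes were lower in replicate 2 than in replicate 1 by a median of -1.62 at 0 h and -0.81 at 4 h. This does not decide either, since members of this list vary together (estimated correlation 0.89) and 1 library stands against 1 at each time. Other differences between the libraries stay open, because CIT2, a gene that cells without functional mitochondria induce, was not higher (285 against 357 CPM at 0 h) while DLD3 was (855 against 490).

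Ribosomes of grr1 stood more often with a tryptophan codon in the A site at 0 h. A few genes with many footprints were excluded as the source, since 97.5% of 277 genes with at least 3 tryptophan codons were higher in grr1 (medians 1.36 and 3.18). The 277 include copies with the same values, such as YFL002W-B and YGR161W-A, so not all of them are separate. Sequence preference at footprint ends was excluded too: the log2 difference peaked at offset 0 (1.21) and was at most 0.14 from 4 codons on. Less tryptophan uptake is a candidate explanation, since the tryptophan permease genes TAT2 (-2.68, adjusted p = 0.000852 by edgeR) and TAT1 (-6.27) were lower in grr1. Of the leucine and histidine codons 0 were higher, and TTA, TTG and CAT were lower. This does not decide it, because the broad-range permease gene AGP1 was low too (378 against 13.1 CPM in grr1 at 0 h), while some permease genes were higher. Permease footprints thus do not show which amino acids ran short. TGG was also only 1 of 9 codons called higher in grr1 at 0 h, and the others code for other amino acids. The increase was thus not limited to tryptophan. Less tryptophan uptake remains a hypothesis, found and tested on the same data. At 4 h the difference at TGG was 0.55 (adjusted p = 0.139, and 0.0028 without grr1 0 h replicate 1 or 2).

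Ribosomal protein and stress genes changed less over time in grr1 than in the wild type. Scaling between libraries was excluded, since it cannot change the difference of -5.39 between the interaction medians of the stress (-2.94) and ribosomal protein (2.45) lists. A lower ribosomal protein level before treatment was excluded as the whole cause, because the list did not end level at 4 h (median 1.49, middle 50% of members 1.38 to 1.63). The grr1 replicate 2 libraries were excluded too, with a median of 2.20 without them. For stress genes a higher level before treatment cannot be told apart from a weaker response, as their median at 4 h was -0.53 with a middle 50% of -0.9999 to 0.07. A weaker or slower response of grr1 cells to tunicamycin, slower growth and an earlier approach to the end of growth on glucose in either culture may each contribute, and were not tested.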

How the results depend on the processing

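The fits without both grr1 replicate 2 or both replicate 1 libraries, those on recovered reads, the P site and the 5′ UTR values without YDR133C were chosen only after the data were seen. Over 10 always-named genes and those named by rule, direction and call held for 120 values with RLE factors, while 1 gained a call and 1 reversed. With total counts 102 held, 5 lost their call, 4 gained one and 11 reversed, and with DESeq2 114 held, 5 lost it, 1 gained one and 1 reversed. Without a filter 122 held, and with a mean of at least 50 counts 110 held and 1 lost its call. With a replicate term within each genotype 76 held, 3 gained a call and 1 lost it. Of the values with 1 library left out, 878 held, 80 lost their call, 7 gained one and 11 reversed; a group with 1 library left is then assumed to vary like the other groups. HAC1, KAR2, RPS7A and RPS7B kept the direction of their changes over time in each alternative that gave a value. HAC1 had none with recovered reads, and RPS7A and RPS7B had none with ribosomal protein genes left out.

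Total counts made the interaction 2168 genes. They put UBP3 at 0.60, BRE5 at 0.13 and IRE1 at 0.096 in the wild type, BRE5 at 0.064 in grr1, and UBP3 at -0.37, BRE5 at -0.064 and TRL1 at -0.039 in the interaction. Between the genotypes they put UBP3 at 0.24 and KAR2 at 0.17 at 0 h, and UBP3 at -0.13 and BRE5 at -0.17 at 4 h. The scaling shifts all genes of a comparison by 1 factor, as its construction requires. IRE1 at 0 h was -0.0031 with RLE factors, -0.012 with DESeq2 and -0.015 with ribosomal protein genes left out; the cause was not tested. A 2-fold minimum left 2104 genes in the wild type, 785 in grr1, 1231 at 0 h and 501 at 4 h, as a stricter limit must. A fit of only the grr1 libraries gave 741 genes, against 1511 in the main fit. One of only the wild-type libraries gave 3642, against 3192. The main fit shares 1 spread per gene between all groups. The grr1 replicates lay further apart (median absolute log2 difference 0.286 at 0 h and 0.272 at 4 h) than those of the wild type (0.154 and 0.195). The shared spread can thus be too small for grr1, which raises its count, and too large for the wild type. Both fits also have fewer samples to estimate the spread, and the part of each in the counts was not tested.

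Without both grr1 replicate 2 libraries, UBP3 was -0.060, BRE5 0.015, IRE1 -0.0038 and the TGG codon 0.018 in grr1 over time. Without both replicate 1 libraries the counts were 990 in grr1 and 1719 at 4 h, IRE1 and MOT2 were -0.18 and -0.038 at 0 h, and BRE5 was -0.0029 at 4 h. Recovered reads of 741 genes gave 572, 269, 385, 260 and 260 genes in the 5 comparisons, and KAR2 at 0.084 at 0 h. The coding counts were fitted for 716 of these genes, and the balance of directions turned between the fits. In the wild type recovered reads called 332 up and 240 down, against 188 and 321 with coding counts. The interaction had 183 and 202 against 222 and 62, and 0 h had 193 and 67 against 135 and 194. Fold changes of the fits correlated at r = 0.998 to 1.00 (across genes). The recovered reads were scaled on their 741 genes alone. A shift common to all genes of a comparison turns the balance of directions and leaves the correlation as it is. Other causes of these changes were not tested.

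With an estimated correlation the list tests gave 0 calls in each of the 5 comparisons, against 14, 17, 18, 18 and 16 with the preset one. Fry, which does not compare a list with other genes, gave 23 in the wild type. With a replicate term over all libraries 80 list results held and 3 lost their call. Without both grr1 replicate 2 libraries 77 list results held and 6 lost their call, and without both replicate 1 libraries 78 and 5. The former were SCF-Grr1 in grr1, phospholipid synthesis and calcineurin targets in the interaction, and phospholipid synthesis, amino acid synthesis and G1/S at 0 h. The latter were TCA cycle and SCF-Grr1 in grr1, pheromone response and a-specific genes at 0 h, and pheromone response at 4 h.

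Codon counts were 1 in grr1 and 17 in the interaction with weighted positions, 3 in the interaction and 1 at 4 h with the genes of higher coverage, and 3 in the interaction with a replicate term. They were 8, 18 and 11 in grr1, the interaction and at 4 h without both grr1 replicate 1 libraries. With the codon in the P site 0 codons passed at 4 h (15 at an unadjusted p under 0.05). TGG was then -0.30 in the wild type, 0.32 in grr1, 0.62 in the interaction and -0.40 at 0 h. CAT and CAC were 0.081 and 0.019 in the wild type and 0.033 and 0.069 at 0 h, and TTA was -0.020 in the interaction and 0.023 at 0 h. These P site values compare another codon by construction. Polarity counts were 1, 0, 1 and 0 in the wild type, grr1, at 0 h and at 4 h with the ends left out. They were 21, 0, 1, 71 and 40 in the 5 comparisons with the 371 genes of higher coverage, and 1, 1 and 2 in grr1, the interaction and at 4 h with a replicate term. The 5′ UTR values kept their order without YDR133C.

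With 1 library left out the number of genes ran from 2387 to 3392 in the wild type, 618 to 1677 in grr1, 638 to 1505 in the interaction, 1170 to 2141 at 0 h and 113 to 1188 at 4 h. Codon counts ran from 1 to 20, 0 to 3, 1 to 12, 2 to 15 and 0 to 8, and polarity counts from 0 to 5, 0 to 0, 0 to 3, 0 to 43 and 0 to 3. Over time in grr1 UBP3 ran from -0.019 to 0.22 and IRE1 from -0.12 to 0.34. At 0 h IRE1 ran from -0.19 to 0.31 and MOT2 from -0.041 to 0.30, and at 4 h UBP3 from -0.00125 to 0.077, BRE5 from -0.21 to 0.30 and TRL1 from -0.25 to 0.22. In simulated data with the depths of these libraries and 1 spread per gene for all groups, the interaction test found 11 of 100 genes changed 2-fold. A missing call thus does not show that values were equal.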

Other observations

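The tests behind the hypotheses on the mitochondrial genome, tryptophan uptake, scaling and levels before treatment were chosen only after the results were seen, and the values here were singled out after they were seen. The grr1 replicates differed in more than mitochondrial genes before treatment. FLO1 and FLO5, which encode flocculins that make cells stick together, held 2.24 and 2.62 CPM in grr1 0 h replicate 1 and 76.7 and 68.1 in replicate 2, and the hexose transporter gene HXT13 4.49 and 77.3. At 4 h the same genes held 6.37, 3.54 and 6.37 in replicate 1 and 89.9, 98.5 and 101.6 in replicate 2. In the opposite direction, MLS1 and ICL1 of the glyoxylate cycle and the gluconeogenic gene PCK1 held 573, 797 and 802 in grr1 0 h replicate 1 and 4.61, 9.80 and 34.6 in replicate 2.

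The amino acid permease genes AGP1, GNP1 and TAT2 were also low in grr1, while 3 of the 22 genes of that list were called higher at 0 h. AGP1, a broad-range permease gene, held 378 CPM in the wild type and 13.1 in grr1 at 0 h, and GNP1, a glutamine permease gene, 430 and 72.7. TAT2 held 110 in the wild type and 17.3 in grr1 at 0 h, and 73.9 and 29.7 at 4 h.

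In the authors' deposited translation efficiency tables, HEF3 (-4.93), TDH1 (-4.63), HNT1 (-4.10), PDC6 (-3.88) and CRN1 (-2.91) had large falls in the wild type, and ULI1 (-2.64) fell while its footprints rose. FUN19 (2.68) rose. In grr1, HNT1 (-3.72), SPP382 (-3.49), HXT4 (-3.03), HEF3 (-2.97) and CRN1 (-2.95) were among the 8 genes that fell. These genes were chosen after their values were seen. UBP3 did not pass in either table (-0.07 in the wild type and -0.44 in grr1).

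Annotated 5′ UTRs held 2.11 ± 0.67 footprints per 1000 coding footprints in grr1 at 0 h and 1.94 ± 0.07 at 4 h (SD, n = 2). In the wild type the values were 1.29 ± 0.14 and 2.297 ± 0.02.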
